A study of Mus musculus with 41 samples.

How the data were processed

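The series holds 41 samples, of which 31 belong to chromatin immunoprecipitation (18 with antibody and 13 inputs) and 10 to RNA sequencing. The RNA samples came with no values and were left out. Antibody libraries fall into embryonic brain (2), fibroblasts with Brn2, Ascl1 and full-length Myt1l (3), with Brn2, Ascl1 and truncated Myt1l (3), with full-length Myt1l alone (2), with truncated Myt1l alone (2), with rtTA only (2), Sin3b (2) and HDAC (2). The 3 libraries of each group with Brn2 and Ascl1 comprise 1 with antibody Myt1la and 2 with Myt1lb, and 2 of the 3 with full-length Myt1l bear the same replicate number. The other Myt1l libraries and the control used Myt1lb. Inputs were used by the authors and carry no list of their own.

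Reads were aligned with Bowtie2 2.2.3 and peaks called with MACS2 2.0.10.20131216 on GRCm38, per the submitters' processing notes. The authors deposited 15 peak lists. The 7 pooled lists were each called on the joined libraries of a group, per the labels and the peak names in the files. The deposited pooled lists give a fold enrichment (a ratio to the input background) and a −log10 q for each peak. The lowest −log10 q kept by the authors differs between the deposited lists, from 1.51 in brain to 19.6 with truncated Myt1l, so both values were used only to rank or filter peaks within a list. The 8 other deposited lists have the layout of a reproducibility comparison of 2 sets of calls, with a −log10 of the irreproducible discovery rate and a score for each set. How the authors made them is not stated. They are called reproducibility lists here. The brain list keeps a discovery rate up to 0.794 and the others stop near 0.15, so brain values from it rest on a looser threshold. The scores of the 2 sets correlate weakly in some lists (Spearman 0.118 in brain and −0.0312 with full-length Myt1l alone). Whether control peaks were removed from them is not stated: of the pooled peaks they lack, 60.5% to 93.7% lie over control peaks, and of those they hold, 0% to 1.56%. Comparisons with the control in these lists are therefore not independent results. The control has only such a list, and the score that ranks it is on another scale than in the others, up to 120008. No input is listed for it, and whether an input was used is not stated; its peaks are wide (median 708 bp) and 10.9% lie on the Y chromosome. Shares over control peaks, and values without them, depend on what this list holds. Read depth is unknown, since no file gives counts, and it limits which peaks could be called.

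The pooled list of each group was the main list, and the rtTA-only list served as the control. Shared meant an overlap of at least 1 bp. A share of a list over another is given with a 95% Wilson interval, which covers counting error over peaks only, and was set against 1000 random moves of the peaks within their chromosomes (one-sided permutation test, smallest p 0.001, Benjamini-Hochberg adjustment over the 49 ordered pairs of lists). Shares of 1 list over 2 others were compared with an exact McNemar test, two-sided, adjusted over 10 comparisons. Shares of different lists were compared with Fisher's exact test, two-sided, and ratios of odds ratios are given with a 95% interval from the log scale. Chance shares near gene ends came from random moves and were tested with an exact binomial test, two-sided. Calls use an adjusted p threshold of 0.05. The random moves spread peaks evenly over each chromosome, so exceeding them does not separate shared binding from shared background sites.

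Genes came from the GRCm38.p6 annotation, with 49980 genes of which 21887 protein-coding genes entered the gene list tests. It gives each gene's start and end but no strand or exons, so distances run to the nearer end of a gene, and neither transcription start sites nor exons are reported. No genome sequence was at hand, so the planned count of a Myt1-family sequence word and the matching of random gene sets on GC content were left out. A gene was bound when a summit lay within 5 kb of one of its ends. The 20 gene lists (signalling pathways, lineages, cell division, corepressor complexes, and ribosomal and olfactory genes as reference lists) named 495 members, of which 493 matched. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, adjusted over 20 lists within each peak list.

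The groups, the main tests, the gene lists, the named genes and most alternatives were fixed before the data were examined. The binomial test, the ratios of odds ratios, the test of the difference between the shares recovered by the truncated protein, the counts at small RNA genes and the counts of lists with peaks in the transgenes were chosen afterwards. The gene-end distance took the place of the planned distance to transcription start sites. Named items are up to 12 genes of the fixed lists with the highest −log10 q in the first list of a comparison, the 10 highest peaks in each class (shared, or first list only), each given by the gene with the nearest end, and always Myt1l, Ascl1, Pou3f2, Hes1, Hes5, Notch1, Sin3b and Hdac1. The rule was applied to the main lists and to the lists without control peaks. The text gives most names from the latter, and the names of all members of a called gene list.

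Alternatives were another definition of overlap (the shorter peak covered to a set share, or summits within 200 bp), the reproducibility lists, peaks with −log10 q of 10 or more, the 500 strongest peaks, removal of control peaks, removal of transgene loci, chance moves within the same gene-end class, a 5 kb window, protein-coding ends only, and other ways to assign peaks to genes (1 kb, nearest within 50 kb, or gene body). Added after the data were seen were a reproducibility rate of 0.05 or less, 10000 random sets matched on gene length, and gene lists without transgene loci. The methods were tested on simulated data. Unrelated lists of the sizes of full-length Myt1l alone and Sin3b were called in 1% of 100 pairs, and planted overlaps of 1.97%, 9.98% and 30.0% of 3096 peaks were recovered as 2.13%, 10.1% and 30.1%. The unrelated lists were placed by the same random moves as the test uses. Their low rate therefore does not cover real lists that share background sites. On 21887 genes, lists without enrichment were called in 0% of cases, and a neuronal list enriched 2 fold or 5 fold in 15% or 70%. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.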

Results

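The series measured where Myt1l, a zinc finger transcription factor of the nervous system, binds the mouse genome, by chromatin immunoprecipitation and sequencing. Myt1l was mapped in embryonic brain and in mouse embryonic fibroblasts 2 days after doxycycline switched on lentiviral genes. The fibroblasts received Brn2 (the protein of Pou3f2), Ascl1 and full-length Myt1l, a mixture that turns fibroblasts into neurons, or the same mixture with a truncated Myt1l of residues 200 to 623. Other fibroblasts received full-length or truncated Myt1l alone. Sin3b and HDAC, parts of histone deacetylase corepressor complexes, were mapped in infected fibroblasts too. A control carried only rtTA, the activator of the doxycycline promoter, and was precipitated with Myt1l antibody.

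The files hold 15 peak lists, 7 pooled ones and 8 of another kind, with no read counts, so the depth of each library is unknown. The pooled lists held 2168 peaks in brain (2 libraries), 5298 with Brn2, Ascl1 and full-length Myt1l (3 libraries), and 1952 with Brn2, Ascl1 and truncated Myt1l (3 libraries). They held 3096 peaks with full-length Myt1l alone and 2818 with truncated Myt1l alone (2 libraries each), 1125 for Sin3b and 429 for HDAC (2 libraries each). The rtTA-only control list (2 libraries) held 9694 peaks. No list can be split by replicate, so every interval covers counting error over peaks only, and each test compares lists, not conditions. The labels of the Sin3b and HDAC libraries name Brn2, Ascl1 and Myt1l, whereas the names of their peak lists refer to full-length Myt1l alone, and this conflict was not resolved. The libraries with Brn2 and Ascl1 mix 2 Myt1l antibodies, whereas brain, Myt1l alone and the control used 1 of them, so every comparison with against without Brn2 and Ascl1 also differs in antibody.

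The first question was how much of each list also appeared without any Myt1l transgene. Of the peaks with full-length Myt1l alone, 71.5% (95% Wilson interval 69.9 to 73.1) overlapped a control peak, as did 58.2% (56.8 to 59.5) with Brn2, Ascl1 and full-length Myt1l. The shares were 68.7% with Brn2, Ascl1 and truncated Myt1l, 46.7% with truncated Myt1l alone, 46.4% in brain, 35.7% for Sin3b and 63.9% for HDAC. Random places gave 0.311% to 1.35%, and all 7 lists exceeded every one of 1000 random moves (one-sided permutation p = 0.001, the smallest these moves can give; adjusted p = 0.001). The strongest peaks shared between lists were among these control sites. One lay 675 bp from the lncRNA gene Gm40031 on chromosome 2 (178639207 to 178639687, GRCm38) and had a fold enrichment of 39.1 with Brn2, Ascl1 and full-length Myt1l. Others lay nearest to Lars2, a mitochondrial leucyl-tRNA synthetase gene, and to Crnde, a long non-coding RNA gene. In the reproducibility lists, a second set deposited by the authors, at most 0.987% of the peaks of any list met a control peak, and whether control peaks had been taken out of those lists is not stated. Values with control peaks removed are therefore given beside the main ones.

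Myt1l occupied gene ends in brain and in 3 of the 4 fibroblast conditions. In brain 19.6% of summits (17.9 to 21.3) lay within 1 kb of either end of an annotated gene. The share was 18.5% (16.9 to 20.3) with Brn2, Ascl1 and truncated Myt1l, 14.2% (13.0 to 15.5) with full-length Myt1l alone and 33.9% (32.2 to 35.7) with truncated Myt1l alone. With Brn2, Ascl1 and full-length Myt1l it was 5.93% (5.32 to 6.60), against 6.23% for random places (exact binomial test, two-sided, p = 0.378). Sin3b had 38.1% (35.3 to 41.0), and HDAC had 11.7% (50 of 429 peaks). Among the 500 strongest peaks the share with full-length Myt1l alone exceeded that with Brn2, Ascl1 and full-length Myt1l by 3.60 points (Fisher's exact test, p = 0.0521), against 8.29 points over all peaks. The rtTA-only control had 5.76%, which did not differ from Brn2, Ascl1 and full-length Myt1l (Fisher's exact test, two-sided, adjusted p = 0.688 over 28 pairs of lists).

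With control peaks removed the gene-end shares rose to 30.7% in brain, 45.0% with Brn2, Ascl1 and truncated Myt1l, 35.1% with full-length Myt1l alone, 58.3% with truncated Myt1l alone and 54.6% for Sin3b. Brn2, Ascl1 and full-length Myt1l stayed at 6.09%. In the main lists truncated Myt1l alone exceeded full-length Myt1l alone by 19.7 percentage points (odds ratio of full-length to truncated 0.323, 95% interval 0.284 to 0.367; Fisher's exact test, adjusted p = 5.05e-71). With Brn2 and Ascl1 the truncated protein exceeded the full-length protein by 12.6 points (Fisher's exact test, adjusted p = 2.10e-53). The odds ratio of truncated over full-length was 1.17 times as high with Brn2 and Ascl1 as without (95% interval 0.951 to 1.43). That ratio became 4.90 (3.66 to 6.56) with control peaks removed, but 0.658 within 5 kb, 0.857 at protein-coding ends and 0.799 among the 500 strongest peaks, so its direction depends on the peaks and window used.

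**Figure D1:**
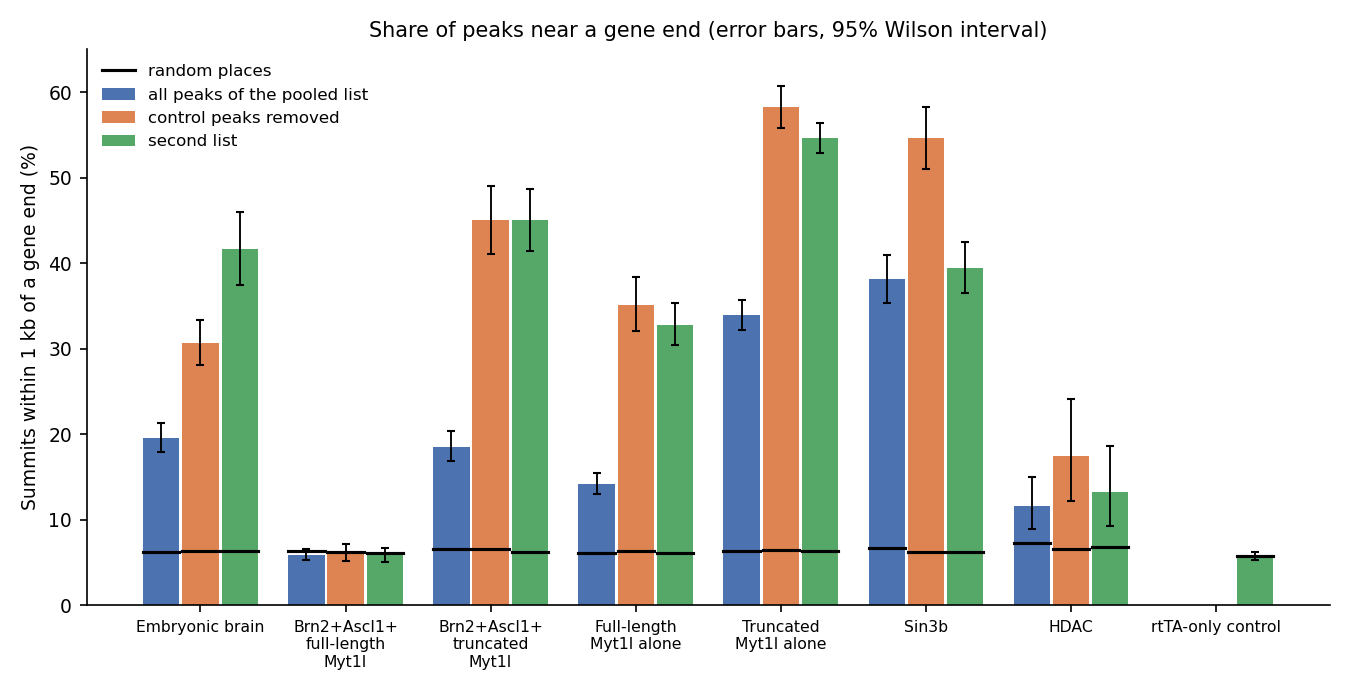
Share of peaks (vertical axis, percent) whose summit lies within 1 kb of a gene end, for each group, in the pooled lists, in the pooled lists without control peaks and in the reproducibility lists, with 95% Wilson intervals; black lines give random places. Brn2, Ascl1 and full-length Myt1l stays at 5.93%, 6.09% and 5.86%, while truncated Myt1l alone reaches 33.9%, 58.3% and 54.6%.

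Small RNA genes were among the gene-end sites, to a degree that differed between lists. In brain 8.76% of summits lay within 1 kb of a protein-coding end and 5.49% at tRNA genes, against 0.00923% at tRNA genes for random places. With truncated Myt1l alone the shares were 27.9% and 2.02%, against 0.0731% at tRNA genes for random places. Genes for tRNA, the adaptors of translation, lay under 119 brain peaks, 101 peaks with Brn2, Ascl1 and truncated Myt1l, 82 with full-length Myt1l alone and 57 with truncated Myt1l alone, out of 430 annotated tRNA genes. They lay under only 6 of the 5298 peaks with Brn2, Ascl1 and full-length Myt1l, 1 Sin3b peak, 1 HDAC peak and 1 control peak. With control peaks removed, tRNA genes lay under 97 of 611 peaks with Brn2, Ascl1 and truncated Myt1l (15.9%, against 6.35% in the reproducibility list) and 118 of 1161 in brain, but under 0.180% of peaks (0.0702 to 0.463) with Brn2, Ascl1 and full-length Myt1l. Genes annotated as snRNA lay under 32 brain peaks, 16 with full-length Myt1l alone and 16 with truncated Myt1l alone, 4 with Brn2, Ascl1 and truncated Myt1l (12 of 709 in the reproducibility list) and none with Brn2, Ascl1 and full-length Myt1l. Peaks were assigned to a small RNA gene when the summit lay within 200 bp of it. Such genes exist in near-identical copies, so which copy was bound is uncertain.

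**Figure D2:**
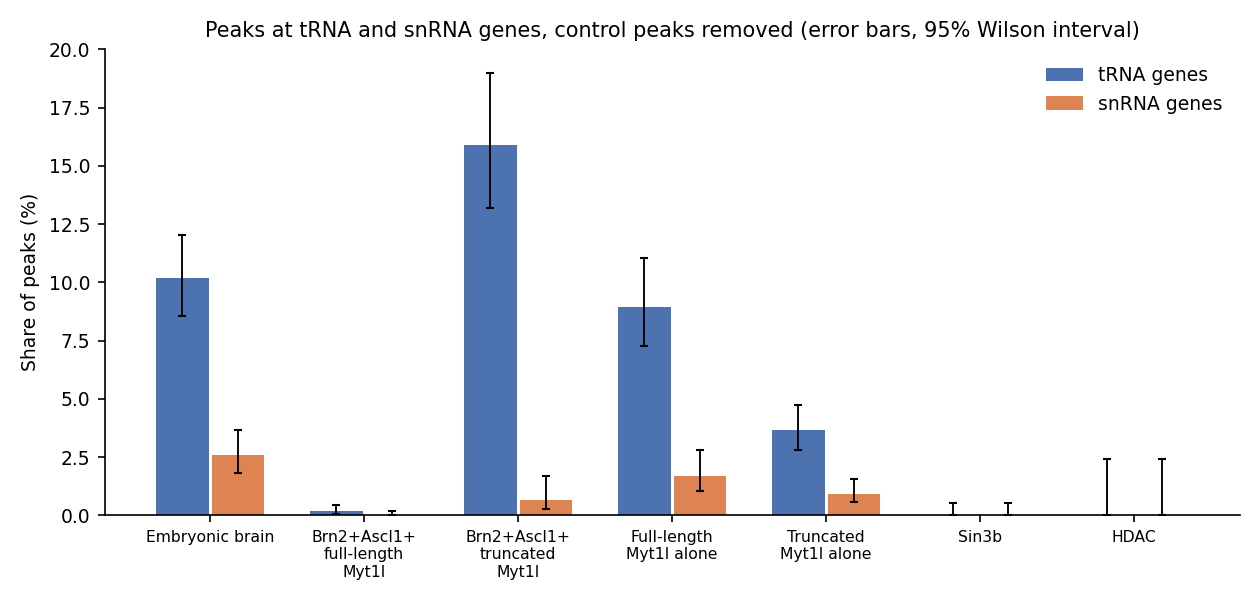
Share of peaks (vertical axis, percent) at tRNA and snRNA genes in each list with control peaks removed, with 95% Wilson intervals. tRNA genes take 15.9% of peaks with Brn2, Ascl1 and truncated Myt1l, 8.96% with full-length Myt1l alone (6.35% and 7.77% in the reproducibility lists, where their order turns) and 0.180% with Brn2, Ascl1 and full-length Myt1l.

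Comparing brain with reprogrammed fibroblasts asks whether the transgene finds the sites of the endogenous protein. Of the brain peaks, 53.7% (51.6 to 55.8) overlapped a peak of fibroblasts with Brn2, Ascl1 and full-length Myt1l, and 51.7% (49.6 to 53.8) overlapped a peak with full-length Myt1l alone. Without control peaks these shares were 16.2% (14.2 to 18.4) and 19.3% (17.1 to 21.7). The 10 strongest brain peaks missing from the reprogrammed fibroblasts all lay at small RNA genes. They included Rnu3b1 (chromosome 11, 87443182 to 87443504, fold enrichment 21.3, −log10 q 43.7), Rnu3b4 (fold 19.3), the snRNA gene Gm22317 (fold 18.4), Rnu1a1 (fold 14.2) and the tRNA gene n-TGgcc4 (fold 14.5). Of the shared sites outside control peaks, the strongest lay 1137 bp from the lncRNA gene Gm52861 (chromosome 6, 47739816 to 47740097, fold 11.3), with others inside the Peak1 gene (fold 8.41) and at the tRNA gene n-TStga3 (fold 14.2).

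Among genes of the fixed lists, 11 had a brain peak within 5 kb of an end. Hes1, a repressor that carries Notch signals, had a brain peak 149 bp from its end (chromosome 16, 30065139 to 30065280, fold 4.78), absent from the brain reproducibility list. Others lay near Lfng, which modifies Notch receptors (fold 5.29), Yap1, the Hippo pathway's coactivator (fold 5.06), Rpl38, a ribosomal protein gene (fold 6.89), and the synaptic vesicle gene Syn1 (4885 bp away, fold 5.75). Klf4, Myh2, Grem1, Nrxn3 and Sp7 had brain peaks too, but all 5 were also control sites. No gene list passed the test in brain (0 of 20 by Fisher's exact test with adjustment, and 0 at an unadjusted p under 0.05). Of the Notch genes 2 of 28 were bound, of the neuronal genes 2 of 40 and of the muscle genes 1 of 25, beside 2.42% of all protein-coding genes.

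Both overlap shares exceeded all random moves (permutation test, adjusted p = 0.001). The share of brain peaks over the control list did too, so exceeding them does not separate shared binding from shared background sites. The share over full-length Myt1l alone lay 1.98 points below the share over the reprogramming mixture (exact McNemar test, two-sided, adjusted p = 0.0189). The direction turned with control peaks removed, to 19.3% against 16.2% (exact McNemar test, adjusted p = 0.0264), so no order between them can be given.

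Full-length Myt1l with and without its partner factors was compared to ask whether Brn2 and Ascl1 change where it goes. Of the 3096 peaks with Myt1l alone, 80.3% (78.9 to 81.7) recurred with Brn2 and Ascl1, while 47.1% (45.8 to 48.4) of the 5298 peaks with Brn2 and Ascl1 recurred with Myt1l alone. The recurring peaks numbered 2487 and 2495, so these 2 shares differ through the lengths of the lists. The lowest −log10 q kept also differed (15.5 with Myt1l alone, 12.4 with Brn2 and Ascl1), as did the number of libraries (2 against 3). The longer list therefore does not show that Brn2 and Ascl1 add sites. Without control peaks the shares were 43.2% and 17.3%. The strongest sites found in both and outside control peaks lay 76748 bp from the lncRNA gene D130009I18Rik (fold 11.0 with Myt1l alone), in Arhgap21, a Rho GTPase regulator (fold 10.9), in Cdk5rap2, a centrosome gene (chromosome 4, 70378082 to 70378293, fold 6.14), at the tRNA gene n-TMcat11 (fold 19.9), in the interleukin receptor gene Il31ra (fold 8.18), and 29 bp inside the end of Yap1 (chromosome 9, 8004465 to 8004749, fold 19.2).

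Sites of Myt1l alone that were missing with Brn2 and Ascl1 lay near Tra2a, a splicing regulator (fold 7.44), Ppil3 (fold 17.6), Tob2, an antiproliferative gene (chromosome 15, 81857893 to 81858558, fold 17.2), Rnu3b3 (fold 17.9) and the tRNA genes n-TGgcc4 (fold 16.0), n-TLcag9 (fold 13.6) and n-TSgct2 (fold 14.7). Sites found with Brn2 and Ascl1 but not with Myt1l alone included 1 inside Msl2 (fold 6.84) and several around the pseudogene Gm3318 near the start of chromosome 10 (fold 5.37 to 5.63). Hes1 (fold 8.95) and Notch1 (chromosome 2, 26503925 to 26504388, fold 13.3) had end peaks with Myt1l alone and none within 5 kb of an end with Brn2 and Ascl1.

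The Hippo and Yap genes were bound more often than other genes with full-length Myt1l alone: 5 of 19 (Ajuba, Amotl2, Stk3, Wwtr1 and Yap1) against 2.66% of other protein-coding genes (odds ratio 13.1, 95% interval 4.69 to 36.4; Fisher's exact test, two-sided, adjusted p = 0.00232 over 20 lists). Wwtr1 encodes Taz, the relative of Yap. With control peaks removed 4 of 19 remained (Fisher's exact test, adjusted p = 0.00469). Of the fibroblast and matrix genes 2 of 30 were bound (Fn1, fold 10.6, and Prrx1, fold 12.3), of the Notch genes 2 of 28, of the Wnt genes 2 of 35 (Fzd1, and Tcf7l1 with fold 10.6), of the muscle genes 1 of 25 and of the cardiac, liver and blood genes 0 of 20 each, none past the test. In the reproducibility list the fibroblast and matrix genes did pass, at 5 of 30 (Col3a1, Fn1, Prrx1, Snai2 and Sparc; Fisher's exact test, adjusted p = 0.00537), as did the Wnt genes at 4 of 35 and the cell division genes at 4 of 30. Cdkn1a, the cell cycle inhibitor p21, had a site 3278 bp away with Myt1l alone (fold 8.05) and 3295 bp away with Brn2 and Ascl1 (fold 5.90). With Brn2, Ascl1 and full-length Myt1l no list passed (1 of 20 at an unadjusted p under 0.05): of the proneural genes 3 of 25 were bound (Ascl1, Pou3f2 and Pou3f3), of the muscle genes 2 of 25 (Myh2 and Pax7), and of the liver genes 1 of 20 (Afp).

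Both overlaps exceeded every random move (permutation test, adjusted p = 0.001), as did the overlaps of both lists with the control, so shared background sites could give this outcome too. A gene list enriched 2 fold was called in only 15% of simulations on the neuronal list, so lists that missed the threshold are not shown to lack binding.

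The comparison of full-length with truncated Myt1l tests what the residues outside 200 to 623 add. Of the peaks with full-length Myt1l alone, 51.9% (50.1 to 53.6) recurred with truncated Myt1l alone, and of the peaks with Brn2, Ascl1 and full-length Myt1l, 28.8% (27.6 to 30.0) recurred with the truncated protein and the same partners. Outside control peaks, truncated Myt1l alone had its strongest shared site 8 bp from the end of Stx16, a membrane fusion gene (chromosome 2, 174075318 to 174076684, fold 29.2), followed among protein-coding genes by Arhgap21 (fold 10.8), the mitochondrial ribosome gene Mrpl44 (fold 24.6) and Tob2 (fold 24.1). Of the 10 strongest sites it had beyond the full-length protein, 8 were ends of protein-coding genes: Mtg1 (fold 24.9), Ap1g1 (fold 22.5), Ighmbp2 (fold 21.9), Tmem242 (fold 21.7), Nme1 (fold 21.4), Nsl1 (fold 20.9), Dmap1 (fold 20.1) and Drg2 (fold 19.1), each within 95 bp. With Brn2 and Ascl1 the truncated protein's own sites were led by tRNA genes, among them n-TMcat10 (chromosome 13, 21931067 to 21931336, fold 14.6), n-TSgct2 (fold 12.6) and n-TVcac7 (fold 14.7). Full-length sites that the truncated protein lacked lay at Foxc2, a mesenchymal transcription factor gene (chromosome 8, 121115915 to 121116284, fold 13.6), in the muscle gene Fhl1 (fold 13.9), near Cdkn1a (fold 8.05) and, with Brn2 and Ascl1, near Eci2 (fold 7.41), in Cmas (fold 8.32) and near Gstm7 (fold 14.4).

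Truncated Myt1l alone reached 4 gene lists, and bound 6.65% of all protein-coding genes. The ribosomal genes, the reference list of broadly active promoters, were among the 4. The other calls are therefore not shown to be particular to their pathways. Of the Notch genes 7 of 28 were bound (Hes1, Maml2, Maml3, Notch1, Notch2, Notch3 and Rfng; odds ratio 4.70, Fisher's exact test, adjusted p = 0.0130), with fold enrichments of 9.90 at Hes1, 11.0 at Notch1, 13.4 at Maml2 and 12.6 at Maml3. Of the Sin3 and HDAC complex genes 8 of 22 were bound (Hdac1, Hdac3, Ing2, Kdm1a, Mta2, Rbbp4, Rcor1 and Sin3a; odds ratio 8.06, Fisher's exact test, adjusted p = 0.00104), with fold 15.5 near Sin3a and −log10 q 25.1 near Hdac1. Of the ribosomal protein genes 9 of 35 were bound (odds ratio 4.88, exact test, adjusted p = 0.00362), among them Rpl3, Rpl8, Rplp0, Rps11 and Rps18 (fold 16.9), and of the Hippo and Yap genes 5 of 19 (odds ratio 5.03, adjusted p = 0.0343). By the same exact test the Hippo call ended with control peaks removed (adjusted p = 0.227) and in the reproducibility list (adjusted p = 0.261). The Notch call ended in the reproducibility list (exact test, adjusted p = 0.0617), and the Sin3 and HDAC call ended when only summits within 1 kb of a gene end counted (adjusted p = 0.206). The ribosomal call (exact test, adjusted p = 0.343) and the Sin3 and HDAC call (0.569) ended when each peak went to the nearest gene within 50 kb. The reproducibility list of truncated Myt1l alone called 5 lists: the Sin3 and HDAC (9 of 22) and ribosomal genes (13 of 35), and besides them the TGF-beta and BMP (8 of 31), neural stem (6 of 20) and cell division genes (8 of 30). Other genes of the fixed lists with strong truncated Myt1l peaks were Nog, a BMP antagonist (fold 15.5), Ctnnb1, beta-catenin (−log10 q 33.2), and Col5a2, a collagen (fold 11.8). With Brn2, Ascl1 and truncated Myt1l no list passed (0 of 20 at an unadjusted p under 0.05), with 2 of 28 Notch genes bound: Hes1 (fold 7.44) and Maml2 (fold 9.11).

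The share recovered by the truncated protein was 23.1 points higher without than with Brn2 and Ascl1 (Fisher's exact test, two-sided, p = 9.11e-98), and 29.0 points higher with control peaks removed (346 of 882 against 227 of 2217 peaks). Among the 500 strongest peaks of each list the difference was 2.60 points (Fisher's exact test, p = 0.438). The lengths of the lists limit these shares, since 1952 truncated peaks were set against 5298 full-length peaks with Brn2 and Ascl1, and 2818 against 3096 without.

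**Figure D3:**
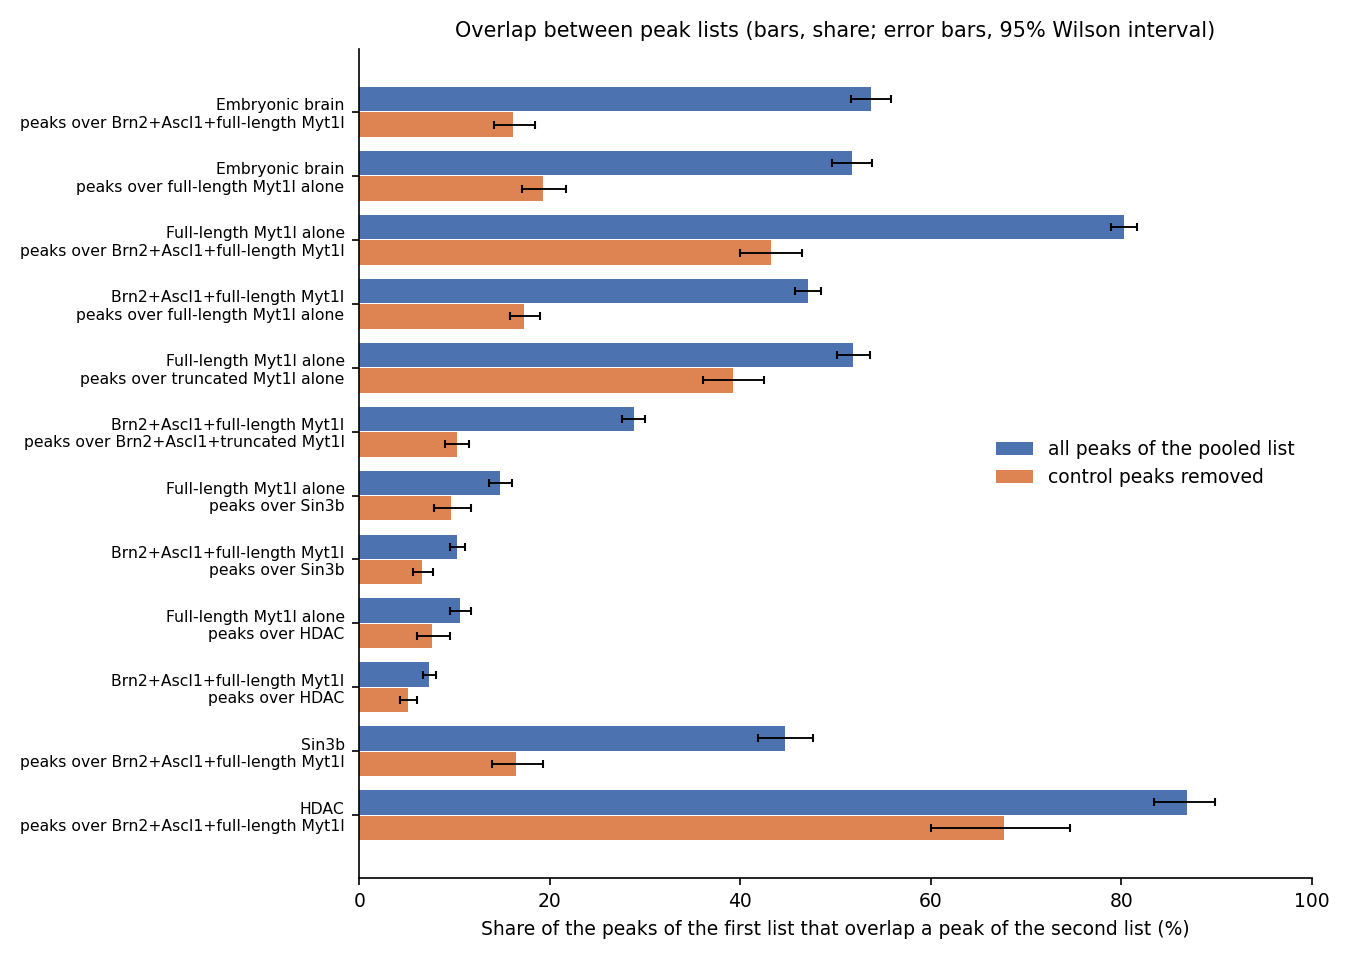
Share of the peaks of the first list that overlap a peak of the second list (horizontal axis, percent), for all peaks of the pooled lists and with control peaks removed, with 95% Wilson intervals. Shares fall when control peaks are removed, for example from 53.7% to 16.2% for embryonic brain over Brn2, Ascl1 and full-length Myt1l.

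Sin3b and HDAC were mapped to ask whether Myt1l sites carry corepressor. Of the peaks with full-length Myt1l alone, 14.8% (13.6 to 16.1) overlapped Sin3b and 10.6% (9.56 to 11.7) overlapped HDAC. With Brn2, Ascl1 and full-length Myt1l the shares were 10.3% (9.48 to 11.1) and 7.34% (6.67 to 8.08), and 5.66% of those peaks overlapped both. Removing control peaks lowered the Sin3b and HDAC shares to 9.64% and 7.60% with Myt1l alone. With Brn2, Ascl1 and full-length Myt1l it lowered them to 6.63% and 5.10%. Seen from the other side, 86.9% (83.4 to 89.8) of HDAC peaks and 44.7% (41.8 to 47.6) of Sin3b peaks overlapped Myt1l bound with Brn2 and Ascl1. Without control peaks these were 67.7% (105 of 155 peaks) and 16.5% (13.9 to 19.3). HDAC peaks were clustered, with 81 of 429 on chromosome 11 (73 of 203 in the reproducibility list). Of the 155, 87 fell in or within 200 bp of only 36 protein-coding genes. The HDAC shares thus count neighbouring peaks separately and do not give a share of separate regions. HDAC peaks overlapped Sin3b in 73.9%, and Sin3b peaks overlapped HDAC in 26.0%.

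Outside control peaks, sites shared by Myt1l and both corepressors lay in Cdk5rap2 (fold 8.61 for HDAC, 6.38 for Sin3b), in Mdga2, a neuronal adhesion gene (chromosome 12, 67059135 to 67059939, fold 6.95 for HDAC), and in Litaf (fold 7.44 for HDAC). Each of these regions carried a peak in 6 of the 7 lists, all but brain, truncated Myt1l included. Whether they give signal with any antibody was not tested, so they are not shown to be joint targets. The strongest Sin3b site shared with full-length Myt1l alone lay at Hjurp, a centromere assembly gene (chromosome 1, 88277145 to 88277721, fold 30.0), ahead of Arhgap11a (fold 31.2 at a lower −log10 q). The 10 strongest Sin3b sites not shared with full-length Myt1l alone lay nearest to Efcab11 (fold 44.0), Smc2 (fold 42.1), Gtse1 (fold 37.9), Iqgap3 (fold 36.3), Hrob, Cdca5 and Bub1 (fold 35.1 each), Esco2 (fold 34.4), and Cdk1 and the histone gene H3c15 (fold 33.5 each). Smc2 encodes a condensin subunit and Esco2 a cohesin acetyltransferase, and Bub1 and Cdk1 belong to the fixed list of cell division genes.

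The cell division list was bound by Sin3b at 12 of 30 genes (Aurka, Bub1, Ccna2, Ccnb1, Cdc20, Cdk1, Cdkn1b, Cdkn2a, Mcm5, Mki67, Plk1 and Top2a) against 2.69% of other genes (odds ratio 24.1, 95% interval 11.6 to 50.3; Fisher's exact test, adjusted p = 1.78e-10). Bub1, Cdk1, Ccna2 (fold 29.6), Ccnb1 (fold 22.0) and Plk1 (fold 15.3) had Sin3b peaks that overlapped no Myt1l peak. HDAC reached the proneural list through 2 of 25 genes, Ascl1 and Pou3f2 (exact test, adjusted p = 0.0358), both named as transgenes in the labels of these libraries, and no list passed once peaks inside the transgenes' own genes were removed. Sox2, a neural stem cell gene, had an HDAC peak 1181 bp from its nearer end (chromosome 3, 34651158 to 34651371, fold 9.12).

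Every overlap of this comparison exceeded all random moves (permutation test, adjusted p = 0.001). Overlaps of these lists with the control did too, so exceeding them does not separate shared binding from shared background sites. The control list took a larger share of Myt1l peaks than Sin3b did: Sin3b lay 47.9 points lower with Brn2 and Ascl1 and 56.7 points lower without (10.3% against 58.2%, and 14.8% against 71.5%). The control list is also longer and wider than the Sin3b list (9694 peaks over 7001 kb against 1125 over 558 kb), which by itself raises its share. The reproducibility lists, nearly free of control peaks, cannot serve for this comparison. Sin3b took 2.93 points more than HDAC of the peaks with Brn2 and Ascl1 (exact McNemar test, two-sided, adjusted p = 1.59e-17) and 4.20 points more of the peaks with Myt1l alone (exact test, adjusted p = 5.09e-14), an order that turned among the 500 strongest peaks. The Sin3b list is longer than the HDAC list (1125 peaks over 558 kb against 429 over 211 kb), which by itself raises its share.

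The genes carried by the viruses were examined separately. Ascl1 (chromosome 10, 87490819 to 87493660) had a peak inside the gene in 4 of the 4 lists whose labels name the Ascl1 virus, with fold 7.07 with full-length Myt1l, 11.6 with truncated Myt1l, 6.28 for Sin3b and 18.7 for HDAC. It had none in the other 4 lists. In the reproducibility lists only 2 of the 4, those of truncated Myt1l and Sin3b, had one. Pou3f2 had one in 3 of 4 against 0 of 4 lists. Inside Myt1l (chromosome 12, 29527590 to 29923216) full-length Myt1l alone had 9 peaks between 29811377 and 29920079, and truncated Myt1l alone had 4, between 29826948 and 29838196. With Brn2 and Ascl1 there were 5 for full-length Myt1l, between 29594192 and 29851749, and 1 for truncated Myt1l. Brain had 1, at 29664934 to 29665090, the rtTA-only control had 1 at 29527673 to 29528370, and the Sin3b and HDAC lists had none. No peak of any pooled list or of the control lay within 5 kb of an end of Hes5 or of Sin3b, and Hdac1 had one only with truncated Myt1l alone, absent from the reproducibility list.

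**Figure D4:**
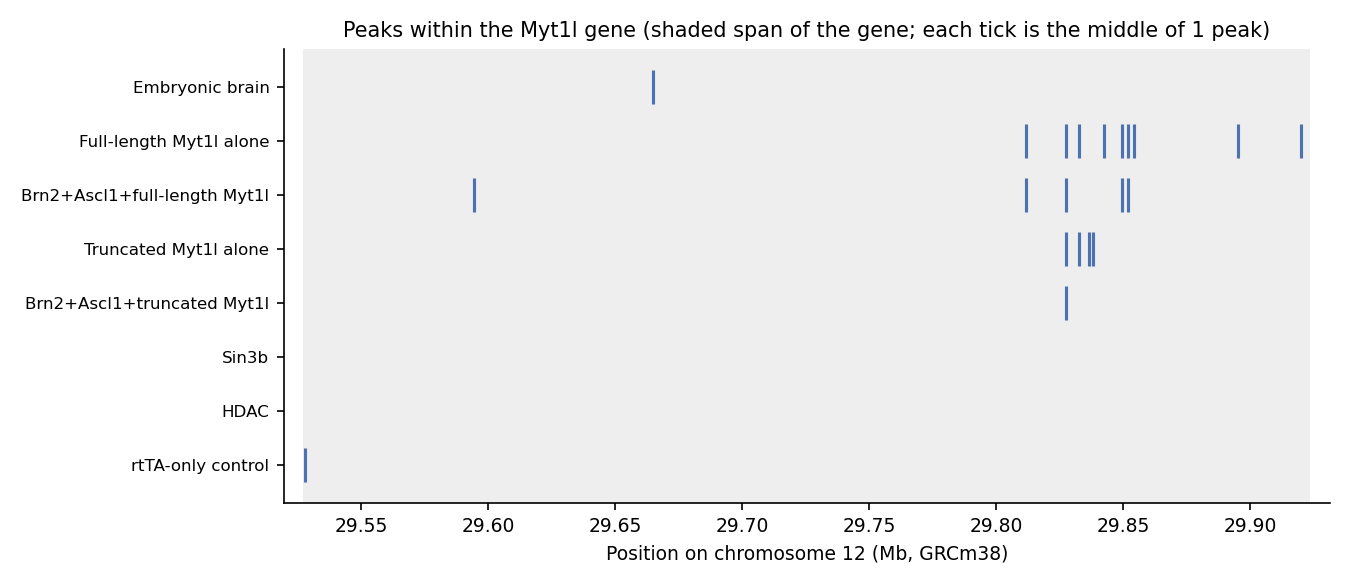
Peaks within the Myt1l gene on chromosome 12 (horizontal axis, Mb, GRCm38), 1 row per list, each tick the middle of 1 peak. The 9 peaks of full-length Myt1l alone span 109 kb and the 4 peaks of truncated Myt1l alone span 11.2 kb.

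The remaining 13 lists were called in no pooled list: Wnt, TGF-beta and BMP, fibroblast and matrix, muscle, cardiac, liver, blood, endothelium, epithelium, cartilage and bone, neural stem, glia and olfactory receptor genes. Truncated Myt1l alone bound the most members in several of these, with 6 of 35 Wnt genes (exact test, adjusted p = 0.106), 5 of 30 fibroblast and matrix genes (adjusted p = 0.115), 4 of 20 neural stem genes (adjusted p = 0.115) and 5 of 31 TGF-beta and BMP genes. The neuronal list was called in the rtTA-only control alone, at 9 of 40 genes (Elavl4, Gabra1, Gap43, Gria2, Map2, Ncam1, Nrxn3, Rbfox1 and Syp; exact test, adjusted p = 0.00239).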

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

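The tests of explanations below, the test of Sin3b overlap by position and the test of the difference in the next sentence were chosen after the results were seen, while the shares themselves were planned. The truncated protein recovered 23.1 percentage points more of the full-length sites without Brn2 and Ascl1 than with them, which stands out as a difference between groups under the same contrast (Fisher's exact test, p = 9.11e-98). The lengths of the lists limit these shares (1952 peaks against 5298 with Brn2 and Ascl1, 2818 against 3096 without), and with the 500 strongest peaks of each list the difference was 2.60 points (Fisher's exact test, p = 0.438), so it cannot be separated from list length. Sin3b overlap also differed between groups: with Brn2, Ascl1 and full-length Myt1l the odds of meeting Sin3b were higher at gene ends than elsewhere (odds ratio 1.95; 17.5% against 9.81% of peaks), and with full-length Myt1l alone they were lower (odds ratio 0.519; 8.86% against 15.8%), a ratio of odds ratios of 3.76 (95% interval 2.37 to 5.96). That ratio was 7.54 with control peaks removed and 11.2 in the reproducibility lists. The same Sin3b list was set against both, so Sin3b itself was not measured in each group. Gene-end peaks numbered 314 of 5298 with Brn2 and Ascl1 and 440 of 3096 without. The ratio may therefore in part restate the fewer gene-end sites with Brn2 and Ascl1.

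The first pattern is the large share of peaks also found in the rtTA-only control. Binding of the Myt1l antibodies to another protein of fibroblasts cannot be the whole of it, since Sin3b peaks, made with another antibody, met control peaks in 35.7% of cases against 1.25% by chance. Virus or fibroblast culture cannot be either, since brain peaks met them in 46.4% against 0.311%. Sites that give signal with any antibody may account for it, but their position does not decide this. Peaks over control peaks lay near gene ends at no more than 1.22 times the chance share in any of the 7 lists, unlike the other peaks of 6 of them. The control list itself lay at the chance share (5.76%), so peaks chosen for overlapping it would do so whatever their source. Background sites in the control list, for which the use of an input is not stated, and weak endogenous Myt1l-family binding in fibroblasts, were not tested.

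The second pattern is that with Brn2, Ascl1 and full-length Myt1l gene-end sites stood at the chance share (5.93%) and tRNA sites were nearly missing, whereas the other 4 Myt1l lists had more of both (among the 500 strongest peaks the gene-end difference to full-length Myt1l alone was 3.60 points, Fisher's exact test, p = 0.0521). Weaker recovery of all sites alike is argued against by the sites of full-length Myt1l alone outside control peaks, split by −log10 q into 4 parts. In the strongest part 15.2% of gene-end sites (9.29 to 23.9, 14 of 92) but 70.5% of others (62.2 to 77.7, 91 of 129) were found with Brn2 and Ascl1. The others may include sites that give signal with any antibody, so a weaker enrichment limited to sites bound by Myt1l is not excluded. For reads shared between near-identical gene copies there was no separate test. After control peaks were removed tRNA genes took 0.180% of that list and at least 3.66% of the other 4, which restates the pattern and decides nothing. Open chromatin at gene ends that any antibody recovers should appear in the control too. The control met 8.27% of gene-end peaks of truncated Myt1l alone and 66.3% of its other peaks. The control list itself lay at the chance share near gene ends (5.76%). Its depth and use of an input are unknown, so it may miss such sites and does not decide this. Mixed antibodies are argued against by Brn2, Ascl1 and truncated Myt1l, which share them and kept 18.5% of peaks at gene ends. Such weaker enrichment, an antibody effect on the full-length protein, and a difference between library batches, for which the labels give no information, may remain. So may a move of full-length Myt1l away from gene ends in the presence of Brn2 and Ascl1. None of these was tested.

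The third pattern is the peaks inside Ascl1, Pou3f2 and Myt1l. Viral copies of the transgenes may be their source, but no value decides it: an Ascl1 peak appeared in 4 of the 4 lists labelled with the virus and 0 of the 4 others (Fisher's exact test, p = 0.0286, a test chosen after the Ascl1 peaks had been seen), in 2 of 4 against 0 of 4 reproducibility lists (exact p = 0.429), and in 2 of 2 against 2 of 6 with Sin3b and HDAC placed by the names of their lists (exact p = 0.429). The lists of full-length and truncated Myt1l, alone or with Brn2 and Ascl1, each held a peak within 29826875 to 29827846 of the Myt1l gene, where brain and the control had none. The rtTA-only control, without that virus, held 1 peak elsewhere in the gene, at 29527673 to 29528370. The Sin3b and HDAC lists, whose labels name Myt1l as well, held no peak in the Myt1l gene. No exons were at hand, so whether such peaks follow the exons of the viral copy is unknown. Binding at the genes themselves cannot be told apart from this, because 0 of the 3 Myt1l lists without the Ascl1 virus had an Ascl1 peak and binding that needs Brn2 and Ascl1 would give the same picture.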

How the results depend on the processing

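Results from the reproducibility lists at a rate of 0.05 or less, length-matched sets and gene lists without transgene loci were chosen after the data were seen. No paired analysis was possible because each list was called on joined libraries, and for the same reason no replicate could be left out; unknown depth limits which weak sites could be called. All 117 repeats of the tested overlaps between lists kept their direction and stayed past the threshold, though the share of brain peaks over Brn2, Ascl1 and full-length Myt1l ranged from 11.1% to 81.5%. This count does not measure robustness. Outside brain and HDAC every pooled peak had a −log10 q of at least 12.4, so the filter at 10 removed none and repeated the main result. All repeats were set against random moves, which do not separate shared binding from shared background sites. The reproducibility lists hold few control peaks, which may have been removed from them, so the next values are no independent result. In them the shares over the control fell below chance: brain 0%, Brn2, Ascl1 and full-length Myt1l 0.180%, full-length Myt1l alone 0.216%, truncated Myt1l alone 0.264%, and at a rate of 0.05 or less 0%, 0.308%, 0.166% and 0.135%. Sin3b had 0.294%, HDAC 0.985% (permutation test, adjusted p = 0.214) and Brn2, Ascl1 and truncated Myt1l 0.987% (permutation test, adjusted p = 0.0296), of which only the last passed. In those lists Sin3b exceeded the control by 7.34 and 9.21 points with and without Brn2 and Ascl1 (9.78 and 13.0 points at the stricter rate), against −47.9 and −56.7 in the main lists.

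Among the 500 strongest peaks, Sin3b minus HDAC turned to −11.2 points with Brn2 and Ascl1 and −8.60 points for Myt1l alone. The share of Sin3b peaks over Myt1l with, minus without, Brn2 and Ascl1 turned to −2.80 points and that of HDAC peaks fell to 2.56 points (exact McNemar test, p = 0.169). The difference of full-length sites recovered by the truncated protein fell to 2.60 points (Fisher's exact test, p = 0.438), and the gene-end difference of Myt1l alone and with Brn2 and Ascl1 to 3.60 points (p = 0.0521). The share of full-length Myt1l alone over truncated minus over Brn2, Ascl1 and full-length Myt1l was 14.8 points in the reproducibility lists, 8.14 at the stricter rate and −3.97 without control peaks (exact p = 0.108). HDAC peaks over Sin3b minus over Myt1l with Brn2 and Ascl1 gave 2.96 points in the reproducibility lists, 6.06 among the 500 strongest, −1.29 without control peaks (exact p = 0.885) and 0 at the stricter rate. Brain peaks over Myt1l alone minus over Brn2, Ascl1 and full-length Myt1l turned to 25.0 points in the reproducibility lists, 75.6 at the stricter rate, 11.0 at −log10 q of 10 or more, 6.60 among the 500 strongest and 3.10 without control peaks.

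The gene-end share with Brn2, Ascl1 and full-length Myt1l was 23.4% within 5 kb (exact binomial p = 0.369), 6.60% among the 500 strongest (p = 0.506), both just above chance, and 2.23% at protein-coding ends, below chance (p = 9.20e-05). HDAC at protein-coding ends had 5.13% (exact p = 0.402). The ratio of odds ratios for gene ends was 0.658 within 5 kb, 0.857 at protein-coding ends, 0.799 among the 500 strongest, 4.90 without control peaks, and 5.32 and 4.02 in the reproducibility lists and at the stricter rate. Gene lists called with the nearest gene within 50 kb numbered 5 for Brn2, Ascl1 and full-length Myt1l, 4 for full-length Myt1l alone and 0 for HDAC. With gene bodies they numbered 1 for brain, 2, 3 and 0. In the reproducibility lists they numbered 4 for full-length Myt1l alone, 5 for truncated Myt1l alone (4 in the main list) and 0 for HDAC, and HDAC had 0 with length-matched sets and with transgene loci removed. The ribosomal and Sin3 and HDAC calls of truncated Myt1l alone ended with the nearest gene within 50 kb (exact test, adjusted p = 0.343 and 0.569). For changes not explained by the smaller lists themselves, the cause was not tested.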

Other observations

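The counts below were made after the data were seen. Outside control peaks, 9 merged regions carried a peak in all 7 lists and 33 in 6, while 4254 carried a peak in 1 list. Of the 9, 4 lay within Sfi1 on chromosome 11 between 3131908 and 3166207, 1 in Smo, a Hedgehog receptor gene (chromosome 6, 29747670 to 29749178), 1 in Hexb, a lysosomal enzyme gene (chromosome 13, 97190448 to 97190719), 1 at the rRNA gene n-R5s194 and 1 at Mir6236. The last lay 105031 bp from the lncRNA gene Gm28590 on chromosome 1. Ribosomal RNA genes lay under 43 peaks with Brn2, Ascl1 and truncated Myt1l and 20 brain peaks, out of 65 annotated, and under 6 with Brn2, Ascl1 and full-length Myt1l, 7 with full-length Myt1l alone and 6 with truncated Myt1l alone. In the reproducibility list of Brn2, Ascl1 and truncated Myt1l they lay under 5 of 709 peaks.

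Sin3b met Myt1l less often at gene ends than elsewhere in 4 of the 5 Myt1l lists. Of the gene-end peaks of truncated Myt1l alone 5.45% overlapped Sin3b, against 21.4% of its other peaks (Fisher's exact test, two-sided, p = 1.07e-31), and with Brn2, Ascl1 and truncated Myt1l the shares were 13.0% and 25.7% (p = 6.75e-08). In brain they were 6.37% and 13.9% (exact p = 8.35e-06), a difference that vanished without control peaks (3.65% and 3.60%). The control list had 1061 of its 9694 peaks on the Y chromosome (10.9%), and the pooled lists 1.98% to 3.97%.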
